A study of Camponotus floridanus and Atta cephalotes and Atta sexdens with 49 samples.

How the data were processed

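Antennal poly(A) RNA was sequenced from 3 ant species. Per the labels' protocols, antennae were frozen and ground, RNA was extracted with TRIzol and treated with DNase, and libraries were made with a NEBNext Ultra II RNA kit; that kit name does not state that strand was kept, and counting did not use strand. For C. floridanus and A. cephalotes the deposited values are raw read counts per gene, 1 file per library. Per the file headers, these counts were made with featureCounts 2.0.0 on coding sequence features, with default options for strand, multi-mapping and overlapping reads; TopHat2 2.1.1 and Bowtie2 2.2.9 are named in the submitters' processing notes, which also name DESeq2 1.38.3 without saying which test was run. Per the file headers the C. floridanus annotation was that of assembly Cflo_v7.5; the A. cephalotes build is not given in the sources used here. Reads on overlapping or antisense genes cannot be told apart without strand, and with multi-mapping reads not counted, near-identical copies in an array lose reads to an unknown extent. For A. sexdens the deposited values are estimated counts per assembled transcript, in the layout of a salmon output with Trinity transcript names per the file headers; the versions and settings are not given in the sources used here. The TPM column deposited in the same files by the authors was used only to check the files.

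Samples were grouped by species and by the group abbreviation in their titles. The 8 comparisons were Mj against Mn in C. floridanus, Sol against For in A. sexdens, and the 6 pairs of For, Sol, Mi and DW in A. cephalotes, with a further test over its 4 groups. Counts of A. sexdens transcripts were rounded to whole numbers after summing over the assembler's genes. No pair of libraries of the same group agreed within sampling noise: the lowest chi-square per gene was 4.76 in C. floridanus, 13.21 in A. cephalotes and 93.28 in A. sexdens. Pairs across groups were not compared in this way.

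The main test was edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, the quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment at 0.05, with group as the only term. The A. cephalotes fit held all 4 groups. CPM values are normalised by TMM library sizes except for shares of a library, which are scaled by the total count in genes. On simulated counts with 200 changed genes, the C. floridanus step (9421 genes) recovered 48% of genes changed 1.5-fold, 84% changed 2-fold and 98% changed 4-fold, with 4.1% false calls, and the A. cephalotes Sol against For step (9572 genes) recovered 26%, 76% and 88%, with 3.4% false calls. The A. sexdens step (41221 genes) recovered 0% of genes changed 4-fold and 32% changed 64-fold.

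The rule for named genes was fixed before the data were examined, as were the tests, the main alternatives and 30 gene lists by product name, among them odorant receptors. The 12508 of 12512 C. floridanus identifiers that are numbers after the letters LOC, and all 10491 A. cephalotes identifiers, carry no product names, so these lists had no members, apart from Titin in a list for muscle, and the planned counts of odorant receptors were not computed. Following the rule for that case, the 2 genes higher and the 2 lower with the smallest p are named per comparison, with the 4 descriptive C. floridanus identifiers added. All 12512 C. floridanus identifiers matched the gene table of the reference, which repeats them as symbols.

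Tandem arrays took the place of the lists. They were defined from gene positions after the files were opened and before their values were tested: at least 4 consecutive genes on 1 strand, at most 20 kb apart, with neighbouring coding lengths within a ratio of 1.25, classed as receptor-length when the median coding length was 1000 to 1400 nucleotides. C. floridanus had 76 arrays with 396 genes (shuffled positions gave a median of 32 and at most 87 over 1000 shuffles) and A. cephalotes had 32 arrays with 186 genes (16 and 54), 10 of them receptor-length with 57 genes. In each comparison 4 sets (receptor-length, longer and shorter arrays, and single genes of receptor length) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, and p-values were adjusted over the 4 sets. Library shares were compared by two-sided permutation tests, exact for 5 against 5 and with 100000 resamples for C. floridanus, adjusted likewise. A test of 3 against 3 cannot give an exact p below 0.1, so none was used in A. sexdens.

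The settings varied were RLE size factors, no filter or a stricter filter on low counts (1 CPM), DESeq2 1.42.0, limma voom with quality weights, the shared label number as a replicate block, only the 2 groups compared in the fit, a 2-fold minimum, transcripts as deposited in A. sexdens, and leaving out each library in the groups of 3 to 5. Further settings, chosen after the data were seen, were counts thinned to the smallest library, removal of a length trend, runs of at least 3 genes as arrays, C. floridanus without Mj 9 and Mn 12 (the 2 libraries farthest out on 1 side of the first principal component, with 33.7% of the variance, at -116.8 and -52.5, where the next was Mj 13 at -38.8; Mj 9 also had the lowest TMM factor, 0.75, and 18.64% of its counts in 10 genes), and 3 sets of C. floridanus libraries by label number, alone or as a covariate. Set A holds numbers 1, 2, 3, 4 and 7, set B numbers 8, 9, 10 and 16, and set C numbers 11 to 15; they were defined after a principal component was seen to follow the numbers, and what the numbers stand for is not given in the sources used here. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.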

Results

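The series measured gene expression in the antennae, the main olfactory organ of ants, by sequencing poly(A) RNA from 3 species. Camponotus floridanus is a carpenter ant with workers of different size castes, and Atta sexdens and Atta cephalotes are leafcutter ants whose workers divide tasks by size. The series title names castes, environment and odorant receptors, while the labels give each library's species, an abbreviated group and a number, and no environment; the abbreviations Mj, Mn, Sol, For, Mi and DW are not spelled out in the labels and are kept as given. The 49 libraries fell into 8 groups. C. floridanus had 11 Mj and 12 Mn libraries with 3852788 to 13391999 counted reads each. A. cephalotes had 5 libraries in each of the groups For, Sol, Mi and DW with 4943507 to 26952835 counted reads each, the lowest being Sol 4. A. sexdens had 3 Sol and 3 For libraries with 15784011 to 24768309 estimated reads each. The labelled batch was the same for all libraries of a species and differed between species, so expression was compared only within a species. Nothing in the labels says that libraries of a group came from separate animals or colonies, so the p-values measure only the spread between these samples, which may be technical.

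The first comparison asked which antennal genes differed between Mj and Mn in C. floridanus. Of 9421 genes tested, 1201 were higher and 1007 were lower in Mj, together 23.4% of the genes. Large differences lay on the side of higher expression in Mj: 362 called genes were at least 2-fold higher and 107 at least 2-fold lower, and 86 were at least 4-fold higher against 0 lower. The median absolute log2 fold change of the called genes was 0.67. LOC105248245 (NW_020229536.1, 1139861 to 1141942, minus strand, assembly Cflo_v7.5) reached 166 ± 56.9 CPM (read counts scaled by library size; SD, n = 11) in Mj and 19.2 ± 5.53 CPM (SD, n = 12) in Mn. Its log2 fold change was 3.10 with a standard error of 0.196 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.94e-10). LOC105255579 (NW_020229226.1, 2789518 to 2792122, minus strand) rose from 135 ± 37.9 CPM (SD, n = 12) in Mn to 958 ± 353 CPM (SD, n = 11) in Mj, a log2 fold change of 2.83 ± 0.206 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.29e-09). Among the genes with the smallest p in the other direction, LOC105257785 (NW_020229325.1, 6642243 to 6644913, plus strand) stood at 81.0 ± 11.3 CPM (SD, n = 11) in Mj against 125 ± 13.3 CPM (SD, n = 12) in Mn, and LOC105257348 (NW_020229359.1, 1347101 to 1348273, minus strand) at 28.0 ± 6.44 CPM (SD, n = 11) against 47.0 ± 3.81 CPM (SD, n = 12). Their log2 fold changes were -0.62 and -0.74 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.15e-05 and 2.73e-05). For each of these 4 genes the lowest library of the higher group lay above the highest library of the lower group. When the libraries were divided by their label numbers into 3 sets, set A (4 Mj and 4 Mn) gave 879 genes higher and 593 lower, set C (4 Mj and 5 Mn) gave 1306 and 897, and set B (3 Mj and 3 Mn) gave 0 and 0 with edgeR, with 628 genes at an unadjusted p under 0.05 and 92.8% of the genes called over all libraries on the same side. limma voom with quality weights called 1757 genes higher and 1745 lower.

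Odorant receptor genes of ants are known to lie in tandem arrays of similar genes, but the gene identifiers of these files carry no product names, so odorant receptors were not identified here. Runs of at least 4 neighbouring genes on 1 strand with similar coding lengths were examined instead, and were classed by their median coding length; arrays of 1000 to 1400 nucleotides are called receptor-length arrays, a length typical of insect odorant receptors, without any statement on what the genes encode. C. floridanus had 40 receptor-length arrays with 216 genes, where shuffled gene positions gave a median of 13 genes and at most 42. Of the 162 genes tested, 112 were lower in Mj, 15 were higher and 35 were not called. Their median log2 fold change was -0.78, with the same sign under both scalings, and 138 of the 162 lay below 0. As a set they were lower in Mj than the other genes (camera with a preset correlation, Benjamini-Hochberg adjusted p = 4.78e-21; adjusted p = 0.155 with an estimated correlation, so that call was lost). Among 1625 single genes of the same coding length, 233 were higher and 209 were lower in Mj, with a median of 0.01 (camera adjusted p = 0.886). The median log2 CPM of the array genes per library was 3.01 ± 0.447 (SD, n = 11) in Mj and 3.80 ± 0.299 (SD, n = 12) in Mn (two-sided permutation test, p = 8e-05). Within set A the library medians averaged 2.91 in Mj and 3.50 in Mn, within set B 3.25 and 3.65, and within set C 2.94 and 4.12. The sets gave 60, 0 and 105 array genes lower in Mj by edgeR, with median log2 fold changes of -0.59, -0.33 and -1.11. In set B the library median was 3.75 in Mj 9, and 2.87 and 3.13 in Mj 10 and Mj 16, against 3.62 to 3.72 in Mn.

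**Figure D1:**
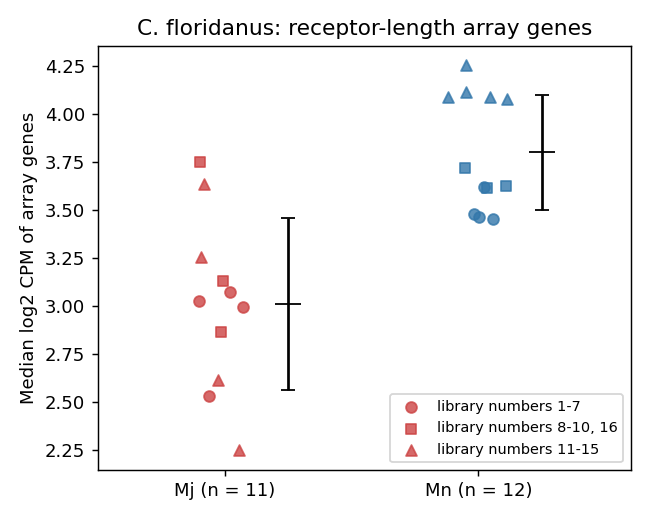
Median log2 CPM of the receptor-length array genes in each C. floridanus library (points, marked by number set), by group on the horizontal axis, with the group mean and its SD. Mj libraries lay between 2.25 and 3.75 (the highest being Mj 9, which also lay apart on the first principal component) and Mn libraries between 3.45 and 4.25, so the groups overlapped in part.

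Whole arrays fell in Mj. On scaffold NW_020229425.1 (Cflo_v7.5) an array at 1259324 to 1302005 had 10 of 10 genes lower, with a median log2 fold change of -1.19, and an array at 1215529 to 1246953 had 7 of 7 lower, with a median of -1.02. Over 952477 to 1391802 of that scaffold 35 of 37 tested array genes lay below 0 with a median of -1.0, and 13 of 22 other tested genes lay below 0 with a median of -0.17. An array on NW_020229281.1 (3519448 to 3557532) had 9 of 9 genes lower with a median of -0.98, one on NW_020229403.1 (1135267 to 1176456) had 8 of 9 lower with a median of -0.81, and one on NW_020229514.1 (105418 to 142649) had 7 of 8 lower with a median of -0.81. A few receptor-length arrays went the other way: all 4 genes of an array on NW_020229214.1 (9678253 to 9697917) were higher in Mj with a median of 1.37, and 3 of 4 tested genes of an array on NW_020229286.1 (82275 to 135911) were higher with a median of 1.02. These arrays were singled out after their values were seen. In that last array, a gene of 1341 coding nucleotides at 100145 to 104077 stood at 1090 ± 494 CPM (SD, n = 11) in Mj against 194 ± 61.1 CPM (SD, n = 12) in Mn, 5.61-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.53e-07). The summed share of the receptor-length arrays was 4462 ± 508 CPM (SD, n = 11) in Mj and 4301 ± 335 CPM (SD, n = 12) in Mn, a ratio of 1.04 (permutation test, Benjamini-Hochberg adjusted p = 0.368), so the sum and the median differed in sign. Reads that map to several similar copies were not counted, so the levels of near-identical genes within an array are uncertain.

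**Figure D2:**
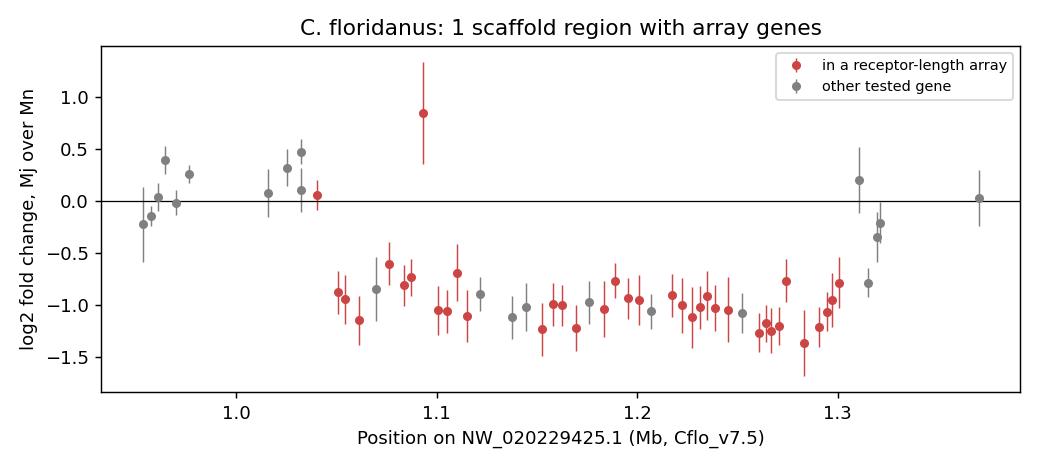
Log2 fold change of Mj over Mn for each tested gene against its position in Mb on C. floridanus scaffold NW_020229425.1 (Cflo_v7.5), with receptor-length array genes and other genes as separate points with standard errors as bars, and 0 as a line. Of the array genes, 35 of 37 lay below 0, and of the other genes 13 of 22.

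Arrays of shorter genes held a small number of very abundant transcripts. Their summed share was 34550 ± 12560 CPM (SD, n = 11) in Mj and 14420 ± 1856 CPM (SD, n = 12) in Mn, a ratio of 2.40 (permutation test, Benjamini-Hochberg adjusted p = 8e-05). Gene by gene there was no common direction: 8 of 34 tested genes were higher, 7 were lower and 19 were not called, with a median log2 fold change of -0.08 against a mean of 0.58 (camera adjusted p = 0.24; adjusted p = 0.555 with an estimated correlation). In Mj, 60.2% of the share came from a gene of 363 coding nucleotides on NW_020229803.1 (1141773 to 1146551, minus strand), which took 3.94% in Mn. Without it the shorter arrays took 13750 ± 3784 CPM (SD, n = 11) in Mj and 13860 ± 2083 CPM (SD, n = 12) in Mn, a ratio of 0.993 (two-sided permutation test, p = 0.942). Scaled by TMM library sizes, that gene stood at 23380 ± 13400 CPM (SD, n = 11) in Mj and 534 ± 508 CPM (SD, n = 12) in Mn, 43.8-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.19e-07). Another gene of 363 coding nucleotides, on NW_020229280.1 (145575 to 157412, minus strand), stood at 506 ± 337 CPM (SD, n = 11) against 11.8 ± 10.8 CPM (SD, n = 12), 42.3-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.69e-07). Both genes, and the share without the first, were singled out after their values were seen.

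Only 4 C. floridanus identifiers were descriptive. Trab and Traa, neighbouring genes related to the sex-determination splicing factor transformer, lie on NW_020229592.1 at 11955 to 18586 and 21589 to 35802. Trab fell from 48.9 ± 9.92 CPM (SD, n = 12) in Mn to 34.1 ± 7.44 CPM (SD, n = 11) in Mj, a log2 fold change of -0.52 ± 0.126 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00393), whereas Traa stood at 219 ± 45.2 CPM (SD, n = 11) in Mj and 233 ± 29.4 CPM (SD, n = 12) in Mn (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.602). Makorin-1, a RING finger protein (NW_020229403.1, 21544 to 33660), had a log2 fold change of 0.21 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.126). The gene labelled Titin (NW_020229825.1, 1080703 to 1087252) is named after a giant muscle protein but had only 4155 coding nucleotides here. It stood at 41.2 ± 23.1 CPM (SD, n = 11) in Mj and 27.4 ± 18.3 CPM (SD, n = 12) in Mn (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.309). The Trab call was lost in each number set alone (log2 fold changes of -0.39, -0.56 and -0.51 in sets A, B and C). Titin passed with the number set as a covariate (0.85) and in set A alone (0.52), and Traa lay above 0 with limma voom (0.03) and in set A alone (0.19).

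The A. cephalotes libraries asked how antennal expression differed among For, Sol, Mi and DW. A test over all 4 groups called 2205 of 9572 genes (23%). Among these genes the highest group mean was most often in Mi (888 genes), then in Sol (673), For (437) and DW (207), and the lowest was also most often in Mi (714 genes) and least often in DW (226). Over all 9572 genes, called or not, the highest mean lay in Mi in 29.1%, in For in 28.1%, in Sol in 26% and in DW in 16.8%, so DW was the least frequent there too and For came before Sol. The lowest mean lay in Mi in 30% of all genes, near the 32.4% among the called genes. For DW these shares were 18.7% and 10.2%. All pairwise tests used the spread of all 4 groups. None of the A. cephalotes identifiers matched a gene symbol in the sources used here, and coordinates are those in the deposited files, whose assembly is not given in the sources used here.

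**Figure D3:**
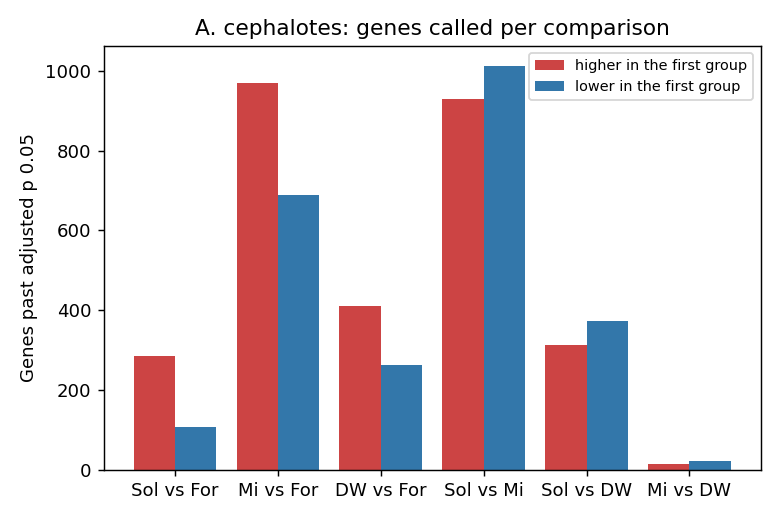
Number of A. cephalotes genes past an adjusted p of 0.05 in each pairwise comparison (horizontal axis), with bars for genes higher and lower in the first group named. In this fit of all 4 groups Sol against Mi had the most calls (929 higher and 1012 lower) and Mi against DW the fewest (15 and 21), while with only the 2 compared groups in each fit Mi against For had the most (1337 and 1193) and Sol against Mi had 746 and 800.

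Between Sol and For, 286 genes were higher and 107 were lower in Sol, of which 88 and 25 differed at least 2-fold. LOC105618350 (NW_012130065.1, 1872221 to 1877306) stood at 404 ± 146 CPM (SD, n = 5) in Sol and 54.7 ± 15.1 CPM (SD, n = 5) in For, 7.37-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.44e-05). LOC105626920 (NW_012130071.1, 3095358 to 3102252) was at 262 ± 120 CPM (SD, n = 5) against 51.1 ± 10.7 CPM (SD, n = 5), 5.11-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.44e-06). LOC105627256 (NW_012130072.1, 4455799 to 4460500) was lower in Sol, at 27.2 ± 6.64 CPM (SD, n = 5) against 81.2 ± 13.1 CPM (SD, n = 5), a log2 fold change of -1.57, and LOC105627038 (NW_012130065.1, 11561414 to 11567139) had a log2 fold change of -1.82 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.59e-05 and 0.000909). Of 49 tested genes in receptor-length arrays, 1 was higher and 2 were lower, with a median of -0.01 (camera adjusted p = 0.311; adjusted p = 0.57 with an estimated correlation). Of 62 tested genes in shorter arrays, 0 were higher and 4 were lower with edgeR, with a median of -0.26 (camera adjusted p = 0.000201; adjusted p = 0.226 with an estimated correlation, so that call was lost). The shorter arrays' summed share was 4409 ± 831 CPM (SD, n = 5) in Sol and 6961 ± 618 CPM (SD, n = 5) in For, a ratio of 0.633 (two-sided exact permutation test, p = 0.00794, the smallest such a test of 5 against 5 can give; Benjamini-Hochberg adjusted p = 0.0317). Most of that share lay in 1 array of 4 genes on NW_012130075.1, at a mean per gene of 977 CPM in Sol and 1590 CPM in For. The genes of this array were not all among those called lower here. This array, and the longer array named for Sol against Mi, were singled out after their values were seen. The counts higher and lower were 145 and 62 without For 1, 173 and 67 without For 4, and 153 and 54 without For 5, and the count lower was 66 without For 2, 59 without For 3 and 65 without Sol 5. DESeq2 called 433 and 197, limma voom 605 and 332, and a fit of the 2 groups alone 187 and 60.

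Between Mi and For, 969 genes were higher and 690 were lower in Mi, of which 161 and 184 differed at least 2-fold. LOC105626834 (NW_012130070.1, 4242006 to 4255153) stood at 108 ± 18.5 CPM (SD, n = 5) in Mi and 45.7 ± 8.27 CPM (SD, n = 5) in For, and LOC105622068 (NW_012130103.1, 147689 to 148772) at 22.3 ± 2.2 CPM (SD, n = 5) and 8.20 ± 0.726 CPM (SD, n = 5). LOC105618023 (NW_012130079.1, 2726135 to 2734961) was lower in Mi, at 43.0 ± 8.98 CPM (SD, n = 5) against 124 ± 11.03 CPM (SD, n = 5), and LOC105627256 stood at 24.9 ± 2.85 CPM (SD, n = 5) in Mi. The differences were 2.37-fold and 2.71-fold for the first pair, and log2 fold changes of -1.52 and -1.71 for the second (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.6e-05, 5.59e-05, 3.52e-06 and 4.52e-06). The receptor-length arrays had 4 genes higher and 4 lower of 49 (camera adjusted p = 0.844). All 4 genes of a shorter array on NW_012130075.1 (4587596 to 4598959, plus strand) were lower in Mi, with a median log2 fold change of -1.61. Their mean per gene was 517 ± 157 CPM (SD, n = 5) in Mi, 898 ± 128 CPM (SD, n = 5) in DW, 977 ± 239 CPM (SD, n = 5) in Sol and 1590 ± 120 CPM (SD, n = 5) in For. The share of all shorter arrays was 2819 ± 704 CPM (SD, n = 5) in Mi against 6961 ± 618 CPM (SD, n = 5) in For, a ratio of 0.405 (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.0317), while 4 of their 62 tested genes were higher, 4 were lower and the median was 0.05. Most of that share lay in the array on NW_012130075.1 in both groups, so its difference was largely that of 1 array of 4 genes. The counts higher and lower were 575 and 354 without For 4, and the count lower was 414 without For 1 and 437 without Mi 4. limma voom called 1759 and 1599, and a fit of the 2 groups alone called 1337 and 1193.

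Between DW and For, 411 genes were higher and 262 were lower in DW, of which 52 and 88 differed at least 2-fold. LOC105627048 (NW_012130072.1, 113859 to 118536) stood at 277 ± 80.0 CPM (SD, n = 5) in DW and 119 ± 16.1 CPM (SD, n = 5) in For, and LOC105618433 (NW_012130080.1, 3872252 to 3879067) at 224 ± 45.5 CPM (SD, n = 5) and 115 ± 12.97 CPM (SD, n = 5). LOC105621741 (NW_012130101.1, 835154 to 840992) was lower in DW, at 266 ± 44.2 CPM (SD, n = 5) against 549 ± 54.6 CPM (SD, n = 5), as was LOC105624003 (NW_012130134.1, 1126910 to 1131250), at 26.1 ± 2.12 CPM (SD, n = 5) against 53.0 ± 6.86 CPM (SD, n = 5). Their log2 fold changes were 1.22, 0.96, -1.04 and -1.02 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00156, 0.00157, 0.00113 and 0.00156). The receptor-length arrays had 1 gene higher and 1 lower of 49 (camera adjusted p = 0.991). The 4 genes of the shorter array on NW_012130075.1 were also lower in DW, with a median log2 fold change of -0.86, and the share of all shorter arrays was 4430 ± 565 CPM (SD, n = 5) in DW, a ratio of 0.637 to For (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.0317), while their genes had a median of 0.18 (camera adjusted p = 0.698). Most of that share lay in the array on NW_012130075.1 in both groups. The counts higher and lower were 155 and 73 without DW 1, 155 and 92 without DW 3, 123 and 81 without For 1, 242 and 149 without For 3, and 103 and 64 without For 4, and the count lower was 158 without DW 2. limma voom called 1322 and 1133, and DESeq2 called 469 lower.

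Between Sol and Mi, 929 genes were higher and 1012 were lower in Sol, of which 326 and 195 differed at least 2-fold and 80 and 31 at least 4-fold. LOC105627599 (NW_012130073.1, 6979660 to 6984922) stood at 435 ± 138 CPM (SD, n = 5) in Sol and 74.0 ± 22.5 CPM (SD, n = 5) in Mi, 5.86-fold, and LOC105623881 (NW_012130131.1, 859314 to 869422) at 4063 ± 1212 CPM (SD, n = 5) and 895 ± 210 CPM (SD, n = 5), 4.54-fold. LOC105618383 (NW_012130080.1, 5674564 to 5711684) was lower in Sol, at 43.5 ± 7.16 CPM (SD, n = 5) against 128 ± 23.4 CPM (SD, n = 5), as was LOC105622960 (NW_012130066.1, 3068171 to 3085427), at 19.3 ± 3.58 CPM (SD, n = 5) against 52.0 ± 5.07 CPM (SD, n = 5). Each of the 4 had an adjusted p of 1.02e-06 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The receptor-length arrays had 6 genes higher and 10 lower of 49, with a median of -0.13 (camera adjusted p = 0.408). The shorter array on NW_012130075.1 had all 4 genes higher in Sol, while all 4 genes of a longer array on NW_012130080.1 (2533097 to 2602842, plus strand) were lower. The mean per gene of the longer array was 31.2 ± 4.52 CPM (SD, n = 5) in Sol and 57.7 ± 8.06 CPM (SD, n = 5) in Mi. Over all shorter arrays 7 genes were higher and 13 were lower of 62 (camera adjusted p = 0.0573; adjusted p = 0.644 with an estimated correlation), and the ratio of summed shares was 1.56 (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.0952). Most of these summed shares lay in the array on NW_012130075.1 in both groups. Without Sol 4 the count higher was 1455, limma voom called 1845 and 1867, and a fit of the 2 groups alone 746 and 800.

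Between Sol and DW, 312 genes were higher and 372 were lower in Sol, of which 121 and 56 differed at least 2-fold. LOC105624426 (NW_012130141.1, 493779 to 520401) stood at 19.9 ± 4.84 CPM (SD, n = 5) in Sol and 4.76 ± 1.22 CPM (SD, n = 5) in DW, and LOC105622801 (NW_012130112.1, 1915919 to 1919101) at 64.7 ± 16.8 CPM (SD, n = 5) and 21.6 ± 5.83 CPM (SD, n = 5). LOC105618383 stood at 95.4 ± 11.9 CPM (SD, n = 5) and LOC105622960 at 39.3 ± 3.79 CPM (SD, n = 5) in DW, and both were lower in Sol. The log2 fold changes were 2.07, 1.57, -1.13 and -1.02 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.85e-05, 0.00014, 0.000282 and 0.00039). The receptor-length arrays had 1 gene higher and 3 lower of 49 (camera adjusted p = 0.423). In shorter arrays 2 genes were higher and 7 were lower of 62, with a median log2 fold change of -0.44 (camera adjusted p = 1.11e-05; adjusted p = 0.272 with an estimated correlation, so that call was lost), while their summed shares had a ratio of 0.995. The counts higher and lower were 741 and 737 without Sol 4, 182 and 193 without Sol 1, 131 and 156 without Sol 3, 196 and 216 without Sol 5, 200 and 233 without DW 1, and 178 and 228 without DW 2, and the count lower was 246 without DW 3. DESeq2 called 531 and 566, limma voom 1007 and 1095, and a fit of the 2 groups alone 124 and 113.

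Mi and DW differed least in number of calls, with 15 genes higher and 21 lower in Mi, of which 6 and 14 differed at least 2-fold. LOC105618350 was lower in Mi, at 36.0 ± 12.5 CPM (SD, n = 5) against 217 ± 110 CPM (SD, n = 5) in DW, a log2 fold change of -2.59, and LOC105617986 (NW_012130079.1, 1514663 to 1517466) stood at 192 ± 50.7 CPM (SD, n = 5) against 428 ± 101 CPM (SD, n = 5), -1.15 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000662 and 0.00372). LOC105626009 (NW_012130068.1, 6219233 to 6222765) was higher in Mi, at 20.97 ± 4.24 CPM (SD, n = 5) against 9.23 ± 2.34 CPM (SD, n = 5), and LOC105625652 (NW_012130067.1, 9169360 to 9236671) stood at 42.3 ± 12.6 CPM (SD, n = 5) against 20.3 ± 4.25 CPM (SD, n = 5); both had an adjusted p of 0.0197 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The receptor-length arrays had 1 gene higher and 0 lower of 49 with edgeR (camera adjusted p = 0.884). The share of the shorter arrays was lower in Mi than in DW, with a ratio of 0.636 (two-sided exact permutation test, p = 0.0159 and Benjamini-Hochberg adjusted p = 0.0476). Most of that share lay in the array of 4 genes on NW_012130075.1 in both groups. Gene by gene 0 were higher and 1 was lower of 62 with edgeR, with a median of -0.06 (camera adjusted p = 0.177). The counts higher and lower were 4 and 5 without Mi 1, 4 and 17 without Mi 3, 3 and 5 without Mi 4, 1 and 5 without Mi 5, 0 and 7 without DW 1, 6 and 15 without DW 2, and 1 and 5 without DW 3, and the calls of LOC105626009 (without Mi 5, DW 1 or DW 3; log2 fold changes of 1.12, 1.10 and 1.09) and LOC105625652 (without Mi 3, Mi 5, DW 1 or DW 3; 0.87, 1.02, 0.995 and 1.07) were lost, as was that of LOC105625652 with a length trend removed (0.92, from 1.06 ± 0.196 (SE); adjusted p = 0.0625). DESeq2 called 77 and 77 genes, limma voom 133 and 97, and a fit of the 2 groups alone called 13 lower and no longer LOC105626009.

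The A. sexdens libraries asked whether antennal transcripts differed between Sol and For in a species whose reads were counted on an assembled transcriptome. No difference was detected: of 41221 assembled genes tested, 0 were higher and 0 were lower by edgeR, with 571 at an unadjusted p under 0.05. limma voom also called 0, and DESeq2 called 11 higher and 2 lower while giving no adjusted p for 23005 genes. The spread between libraries of a group was large, with a biological coefficient of variation of 0.781 against 0.326 in C. floridanus and 0.26 in A. cephalotes. In data simulated from these libraries, 0% of genes changed 4-fold, 2% of those changed 16-fold and 32% of those changed 64-fold were recovered, so moderate differences were not detectable here. The first principal component took 57.9% of the variance and did not separate Sol from For. The files do not pair the assembled genes with names, and none is named here. Without the filter on low counts edgeR called 513 higher and 88 lower, with the median over all genes moved to 1.79 on the log2 scale.

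**Figure D4:**
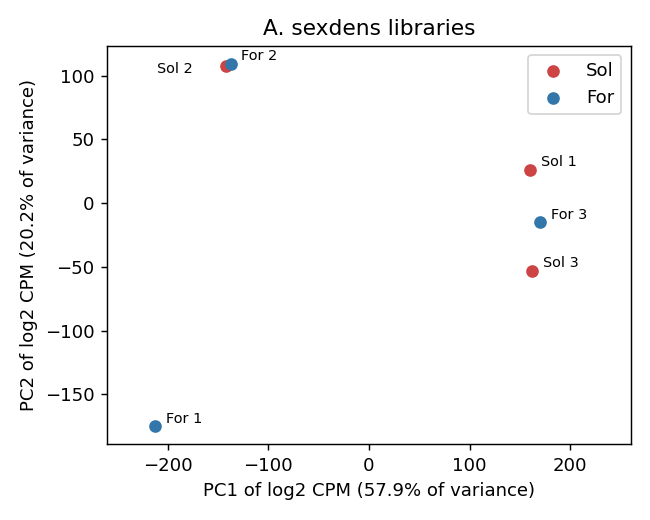
The 6 A. sexdens libraries on the first (57.9% of the variance) and second (20.2%) principal components of log2 CPM, with each point labelled by group and number. For 1, For 2 and Sol 2 lie on 1 side of the first component, and For 3, Sol 1 and Sol 3 on the other.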

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

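Of the tests in this part, the exchange of the labels of Sol 2 and For 3, the count of splits in A. sexdens and the count of contigs with fewer than 20 reads were chosen only after the result was seen.

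Among 112 groups of 5 libraries tested for a library far from the others, 3 had one, where chance gives about 1 in 20. In A. cephalotes, Sol 4, the library with the lowest depth, had 9178 genes with a count, where the nearest Sol library had 9928. On the first and second principal components (23.7% and 17.4% of the variance) Sol 4 lay at -65.7 and -78.3, where the other Sol libraries lay at 18.3 to 32.7 and -24.1 to -7.6; without it Sol against DW gave 741 genes higher and 737 lower, against 312 and 372. Single genes of receptor length took 148300 CPM in Mi 2, where the nearest Mi library had 142100. The TMM factor of DW 2 was 0.959, where the nearest DW library had 1.018.

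The A. sexdens libraries parted in a way that did not follow Sol and For. The split of For 1, For 2 and Sol 2 against For 3, Sol 1 and Sol 3 called 10969 genes, against 0 in the real split and in the other 8; 10 splits are too few for a share under 0.05, and a split with so many calls points to a structure of the samples. The same split had 1800 contigs with at least 20 reads in every library of 1 side and at most 1 read in every library of the other, 16.8 times the median of 107 over the 10 splits and against 46 in the real split, and 151 assembled genes had such contigs on both sides, consistent with transcripts of different source animals assembled separately. Exchanging the labels of Sol 2 and For 3 gives this very split, with its 10969 calls. The number of calls therefore cannot tell a swap from a shared source of each side, since both predict the same value. Whether a swap would also give the 1800 contigs, or the 151 genes with contigs on both sides, was not tested. No labelled group follows this split, but the label numbers follow it in part. For 2 and Sol 2 lay on 1 side and For 3 and Sol 3 on the other, while For 1 and Sol 1 were divided. The correlation of their deviations from the group means was 0.61 for number 2, 0.58 for number 3 and -0.25 for number 1. What the numbers stand for is not given in the sources used here, so no biological explanation was tested.

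A signal also stood in contigs outside the tests: 95664 of 276304 contigs had reads in Sol 1 alone, against 425 to 625 in each of the other libraries alone. A deeper library is argued against, since Sol 1 thinned to the smallest library's total still had reads in 247042 contigs, against 114391 in that library. Chance reads from rare transcripts shared by the other libraries are argued against too: 1462 of these contigs had at least 20 reads in Sol 1 and 0 in the others, against at most 150 such contigs for another library. Most of the 95664 had few reads, with a median of 3; with all libraries thinned to the smallest total, 90553 contigs had 1 to 19 reads in Sol 1 and 0 in the others, against at most 956 for another library. The 95664 contigs held 1.85% of the reads of Sol 1, with a median length of 248 nucleotides against 300 over all contigs. RNA or DNA from another source in that library may account for them, which the files used here, without contig sequences, leave open and untested; no group of the design explains a single library.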

How the results depend on the processing

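The number sets, the fit without Mj 9 and Mn 12, thinning, the length trend and runs of at least 3 genes were chosen only after the data were seen. Of 240 fits of named genes that each left out 1 library, 233 kept direction and side of the threshold and 7 lost the call, all in Mi against DW; of 336 other fits of named genes, 323 kept both, 9 lost the call, 2 gained it and 2 reversed (Traa, 0.028 with limma voom and 0.192 in set A alone). The cause of each change below was not tested, except that a 2-fold minimum calls fewer genes by construction. In the pairs of counts here, genes higher in the first group come first.

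With limma voom the counts were 1757 and 1745 in C. floridanus, 605 and 332 for Sol against For, 1759 and 1599 for Mi against For, 1322 and 1133 for DW against For, 1845 and 1867 for Sol against Mi, 1007 and 1095 for Sol against DW, and 133 and 97 for Mi against DW. DESeq2 gave 11 and 2 in A. sexdens, 433 and 197 for Sol against For, 469 lower for DW against For, 531 and 566 for Sol against DW, and 77 and 77 for Mi against DW. Only the 2 groups in the fit gave 187 and 60 for Sol against For, 1193 lower for Mi against For, 124 and 113 for Sol against DW, and 13 lower for Mi against DW. A 2-fold minimum left 362 and 107 in C. floridanus, 88 and 25, 161 and 184, 52 and 88, 326 and 195, 121 and 56, and 6 higher in the A. cephalotes comparisons in the same order. In C. floridanus, set A alone gave 593 genes lower and 60 receptor-length array genes lower. Set B alone, which holds Mj 9, gave 0 higher, 0 lower and 0 array genes lower by edgeR (628 genes at an unadjusted p under 0.05, and no other tool was run on it). With the number set as a covariate 120 of 162 array genes were lower, and without Mj 9 and Mn 12 121 of 162 (1545 and 1281 calls over all genes); runs of at least 3 genes, a larger set with 201 genes below 0 against 138, gave 142 lower, with a weaker median of -0.67 against -0.78. No filter on low counts gave 513 and 88 in A. sexdens.

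Leaving out 1 library gave 145 to 287 higher and 54 to 106 lower for Sol against For, 575 to 1053 and 354 to 783 for Mi against For, 103 to 600 and 64 to 362 for DW against For, 656 to 1455 and 710 to 1360 for Sol against Mi, 131 to 741 and 156 to 737 for Sol against DW, 0 to 14 and 5 to 31 for Mi against DW, and 0 to 0 in A. sexdens by edgeR (at an unadjusted p under 0.05, 126 without Sol 1, 1155 without For 2, 2792 without Sol 2 and 3534 without For 3, against 571); the A. cephalotes libraries that moved a count by over 1.5 times are named with their values in the results above.

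The label numbers were not taken as pairs, because the labels do not say what they mark and in no comparison was the correlation of the deviations from the group means above 0.1 in every same-numbered pair. In C. floridanus it was 0.05 to 0.67 over 9 pairs, with a median of 0.32 against -0.06 for libraries of different numbers, a hint of shared structure from the data, and 4 of 18 libraries correlated best with their own number. It was -0.29 to 0.36 over the A. cephalotes pairs, and -0.25, 0.61 and 0.58 in A. sexdens, where 4 of 6 libraries correlated best with their own number. With the replicate block the counts were 1261 and 1302 in C. floridanus (104 array genes lower), 0 and 0 in A. sexdens by edgeR (261 at an unadjusted p under 0.05), 267 higher for DW against For, and 5 and 11 for Mi against DW; other counts of calls stayed within 1.5 times. The block also brought the camera adjusted p of the longer C. floridanus arrays to 0.0476 and of the shorter arrays for Sol against Mi to 0.0474; with an estimated correlation and no block these were 0.394 and 0.644, so neither is taken as a call. The planned counts of odorant receptors and list tests were not run, because the identifiers carry no product names. Depth was lowest in Mj 11 (3852788 counts) and in A. cephalotes in Sol 4 (4943507) and Mi 5 (5188798); with counts thinned to the smallest library of each species, the counts of calls stayed within 1.5 times of those reported.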

Other observations

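The longer arrays named here, the tests of neighbouring genes, of the scaling and of the number sets, the correlation between scaffolds within the number sets, the second 50 of the 100 splits drawn for Sol against For and for Sol against DW, the length trend and the count of splits in A. sexdens were chosen only after the result was seen.

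Some longer arrays in C. floridanus held several genes higher in Mj. On NW_020229325.1 (Cflo_v7.5) an array at 6917426 to 6956684 had 6 of 10 genes higher in Mj with a median log2 fold change of 0.83, and an array at 6849105 to 6907747 had 4 of 9 higher with a median of 0.36. An array on NW_020229281.1 (1290383 to 1329420) had 3 of 4 genes higher with a median of 0.88, and an array on NW_020229459.1 (909854 to 937197) had 3 of 6 lower with a median of -0.36. Over all longer arrays 16 of 57 tested genes were higher and 8 were lower, with a median of 0.13 (camera adjusted p = 0.24; adjusted p = 0.394 with an estimated correlation). Their summed share of the total count was lower in Mj, with a ratio of 0.809 (permutation test, Benjamini-Hochberg adjusted p = 0.0001). The log2 fold changes use TMM scaling instead, with factors of 0.75 to 1.016 in Mj and 1.018 to 1.145 in Mn. Total counts thus put Mj lower relative to Mn than TMM does, so the share and the medians are not on 1 scale. The share was not tested with TMM scaling. In A. cephalotes the genes higher in Sol than in For had a median coding length of 2727 nucleotides and those lower 1107, against 1302 over all tested genes; with a length trend removed per library the counts were 222 higher and 115 lower.

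The lower receptor-length arrays in Mj were weighed against 3 explanations. A shift of the scaling is argued against: the lowest median among 1000 sets of single genes matched on coding length and abundance was -0.188, against -0.78 for the arrays. Number sets could hardly give the difference, since they were spread almost evenly over the groups, so this test decides little. Set A held 4 Mj and 4 Mn libraries, set B 3 and 3, and set C 4 and 5. The median stayed below 0 in each set, nearest to 0 at -0.333 in set B, and was -0.75 with the set as a covariate. Within groups, libraries low in the arrays of 1 scaffold were low in those of the others, with a mean correlation between 14 scaffolds of 0.411 against at most 0.291 in matched random sets, and of 0.408 against at most 0.309 with the number sets removed. A smaller RNA share of the cells that use these genes, by labelled group or by dissection, would give this. The random sets were drawn from genes outside the arrays and matched on abundance alone. Genes that move together for any other reason would exceed them too, so the correlation does not single out the cell share. A smaller RNA share of these cells would not by itself give the summed share, 4462 CPM in Mj and 4301 CPM in Mn, a ratio of 1.04 (permutation test, Benjamini-Hochberg adjusted p = 0.368). Nor did all arrays move down: 15 of 162 tested genes were higher and 112 lower, and 2 arrays had medians of 1.37 and 1.02. These 2 points overlap, since the sum weighs abundant genes most. A gene of the last array stood at 1090 CPM in Mj against 194 CPM in Mn (TMM library sizes). The summed share without that gene was not computed. The explanation by a smaller RNA share of the cells thus stays undecided. A lower level per cell in Mj stays open, and whether these genes are odorant receptors was not tested.

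Neighbouring C. floridanus genes were called in the same direction more often than shuffled positions gave. The hypothesis that the arrays alone give this was tested outside them, where 454 neighbouring pairs were called in the same direction, against a median of 248 and at most 298 over 1000 shuffles (permutation p = 0.001, the smallest these can give). The arrays as defined here, with at least 4 genes, are therefore argued against as the only source. Shorter runs of similar neighbouring genes stayed in this count, so it cannot decide on tandem genes in general. Reads of a gene counted to an overlapping neighbour, since strand was not used, may contribute, which was not tested. The excess was not particular to C. floridanus. In A. cephalotes, outside the arrays, Mi against For gave 202 such pairs, against a median of 139 and at most 185 over the shuffles. Sol against Mi gave 273, against 187 and at most 229. Each A. cephalotes comparison lay above its shuffled median, at permutation p of 0.001 to 0.006.

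Other splits of the same libraries were counted for the numbers of calls. Only a part of the possible splits was fitted, 100 of 1352078 in C. floridanus and 50 or 100 of 126 in each A. cephalotes pair. Chance is therefore argued against below rather than excluded. In C. floridanus 1 of 100 splits, the real one, gave 2208 calls and the highest other gave 1137, which argues against chance. Chance is argued against likewise for Sol against For (1 of 100, with 393 against 247). With 1 of 50 splits each, it is argued against for Mi against For (1659 against 0 in the highest other) and Sol against Mi (1941 against 1444). The same holds for Mi against DW (36 against 0) and the 4 groups (2205 against 658). For DW against For the real split also had the most calls of 50, but the split with For 2 in place of DW 4 gave 622 against 673. The real split of DW against For thus barely stood apart from that one, which exchanges 1 pair and so keeps most of the real difference. The highest other splits were also close to the real one for Sol against Mi (Sol 4 and Mi 2 exchanged). In C. floridanus the highest other split had Mj 1 and most Mn libraries on 1 side. These highest values are therefore no measure of chance alone. For Sol against DW, 3 of 100 splits gave as many, with 684 calls in the real split and 1365 in the highest other. Both splits that gave more placed Sol 4 with the DW libraries, in exchange for DW 5 (1365) or DW 4 (1130). For the median of the C. floridanus receptor-length arrays, 1 of 100 splits, the real one, reached -0.778, with the highest other 0.608 from 0. This argues against chance, although the camera call was lost with an estimated correlation (adjusted p = 0.155). For the shorter arrays in Sol against DW, 2 of 100 splits gave a median as far from 0, with -0.441 in the real split and 0.446 in the highest other, and the camera adjusted p was 0.272 with an estimated correlation, so the real split did not stand apart from the highest others. Chance is not argued against for the shorter arrays in Sol against For, where 16 of 100 splits gave a median as far from 0. It was -0.256 in the real split and 0.438 in the highest other. In A. sexdens 10 splits are too few for a share under 0.05, with 0 calls in the real split and 10969 in the highest other.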
